A study of Mus musculus with 4 samples.

How the data were processed

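RNA of mouse liver cell lines was measured on 4 Affymetrix Mouse430_2 GeneChip arrays, each prepared from 5 μg of total RNA with 15 μg of fragmented, biotin-labelled cRNA, per the labels. MMH-D3, a differentiated hepatocytic line, was measured on 2 arrays. The resident liver stem cell (RLSC) group held 2 lines, each on 1 array. MetE14/3 came from the liver of a cyto-Met transgenic embryo at 14 days post coitum (clone B2), and WTE14/1 from a wild-type embryo liver of the same age. Cells with palmate morphology had been expanded for about 50 generations before freezing. The title of the wild-type sample names the line WTE14/1 while its source name reads WT E14/3; the title is used here. The labels do not say whether the MMH-D3 arrays came from separate cultures, so the spread between them may be technical. The p-values measure only the spread between these samples. It also holds the difference between the 2 RLSC lines and, in both groups, that between the array batches described below.

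The deposited values are probe set signals on a linear intensity scale, made by the authors with GCOS, the Affymetrix array software, per the submitters' processing notes. The GCOS version, its algorithm and its settings are not given in the sources used here, and no detection calls were used here. In every array the mean signal without the lowest and highest 2% of probe sets was 200.001, so each array appears to have been scaled by 1 factor to a common target. Median signals were 16.9 and 23.04 on MMH-D3 arrays 1 and 2, 19.6 in MetE14/3 and 27.98 in WTE14/1. The number of arrays limits the precision. All 4 value columns were mapped to a sample.

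The arrays held 45101 probe sets, of which 64 were controls and were left out of tests. Names came from the platform annotation, updated through Entrez identifiers against a RefSeq gene table of assembly GRCm38.p6, which was used for names alone. Of the probe sets, 34958 had 1 symbol, 932 had several and 9160 without controls were unnamed here. Of the first, 34754 matched by Entrez identifier and 0 symbols changed, giving 18194 genes. Probe sets with several symbols or none were tested only at probe set level.

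The following choices were made before the data were examined. Values entered as log2(value + 4), the pseudocount being the rounded 20th percentile of all values, so folds of low genes are understated. Arrays were to be quantile normalized if their medians differed by over 0.25 on the log2 scale. They differed by 0.614, so quantile normalization was applied. Probe sets with a mean below the 40th percentile (a signal of about 11.7) were removed, and each gene was represented by its probe set with the highest mean. RLSC was compared with MMH-D3 by limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment at 0.05. A difference is always RLSC minus MMH-D3 and carries its moderated standard error (SE). The residual degrees of freedom were 2 and the prior ones 4.24. Folds are on the log2(value + 4) scale, while signals are the deposited ones with their SD.

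The 23 gene lists, fixed beforehand from general knowledge, covered hepatocyte, epithelial, mesenchymal and pathway genes and markers of other cell types the cultures could hold. Of their 838 genes, 784 had a probe set named here. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 23 lists. Camera with an estimated correlation and fry were alternatives. Named genes followed a fixed rule. It took the 6 largest differences each way among genes past the threshold whose arrays did not overlap between groups. It added up to 3 passing members of each list, or the 2 members with the highest mean where none passed, and 20 fixed genes, of which 19 had a probe set named here. Between the RLSC lines, with 1 array each, the planned measure was a count without a test. Genes at least 4-fold apart were counted, and the 6 largest each way, up to 2 such members per list and the fixed genes were named. Each list's median was placed among 10000 random lists of the same size matched on mean expression. Members that a paragraph names beyond this rule were chosen after their values were seen.

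Arrays were checked for batches. The 24 poly-A control probe sets were 10.59-fold higher (median; range 5.75 to 26.06) on MMH-D3 array 1 and MetE14/3 than on MMH-D3 array 2 and WTE14/1, while the 18 hybridization control probe sets differed 0.878-fold. The first pair is called batch A and the second batch B. Each batch held 1 array of each group, so the comparison was also fitted with batch as a block and computed within each batch. These fits were added after the controls had been seen. A limma test between the RLSC lines was also added after the results had been seen. It fitted 3 lines on 4 arrays, left 1 residual degree of freedom from the MMH-D3 pair, and assumed that the lone arrays vary as those do.

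The fit was tested on simulated data for 12598 genes with 2 arrays per group, with 200 genes changed in each of 20 simulations. It recovered 1.2% of genes changed 2-fold, 25.2% at 4-fold, 74% at 8-fold and 92.8% at 16-fold, with a mean of 9.5 false calls among 106.1. With the batch block it recovered 38.3% at 4-fold, with 32.8 false calls among 142.8. The test between the RLSC lines, with the same simulated spread, recovered 15.8% at 4-fold, 80% at 16-fold, 98.6% at 64-fold and 99.7% at 256-fold. It made 40.5 false calls among 187.6, so the false share was above the nominal 5% in all 3 fits. The simulated arrays held no batch difference, so recovered and false shares may differ in the data. For lists, camera recovered a shift of -1 in 20 of 20 simulations with 0 false calls, camera with an estimated correlation in 0 of 20, and fry made 2 false calls. The simulated genes varied independently, so these list results do not show how camera behaves with correlated genes. In the data the estimated correlation ran from -0.038 (stellate and mesothelial markers) to 0.942 (cell cycle genes). Alternatives covered the normalization, pseudocount, filter, probe set rule, variance model, threshold, gene set test and each array left out. Figures were drawn with matplotlib 3.10.9.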

Results

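Gene expression was compared between resident liver stem cell lines (RLSC) and MMH-D3, a differentiated hepatocytic line of mouse liver. The RLSC lines were MetE14/3, from a cyto-Met transgenic embryo, and WTE14/1, from a wild-type embryo. The data were 4 arrays, 2 of MMH-D3 and 1 of each RLSC line. Across all probe sets, Spearman correlations of signal were 0.863 between the MMH-D3 arrays and 0.879 between the RLSC lines, against 0.838 to 0.86 between arrays of different groups. Batch A held MMH-D3 array 1 and MetE14/3, and batch B held MMH-D3 array 2 and WTE14/1.

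The first comparison asked how RLSC differed from MMH-D3. Cyba, Fstl1, Myh10 and Tagln were higher in RLSC and Apob, Rbp4 and Crip1 lower. By median, the mesenchymal list was higher in RLSC and the plasma protein and epithelial lists lower. The actin-binding protein gene Tagln, with a mean signal of 1194 ± 1125 in RLSC and 5.02 ± 5.35 in MMH-D3 (SD, n = 2 each), was higher by 6.70 (SE 0.93) on the log2 scale. Apolipoprotein B (Apob), a structural protein of hepatic lipoproteins, stood at 45.2 ± 45.6 in RLSC and 3763 ± 1250 in MMH-D3, a difference of -6.71 (SE 0.85). Of 12598 genes tested with limma, 50 were higher and 65 lower in RLSC. The smallest difference among these 115 genes was 3.91-fold. All 115 had the same direction in both batches, but this follows from the call. Opposite directions would have given a spread too large for a gene to pass.

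With batch as a block, 67 genes were higher and 97 lower, sharing 47 and 64 with the group-only fit. In simulations without batch differences, the blocked fit made 32.8 false calls among 142.8 and the group-only fit 9.5 among 106.1. Both false shares lay above the nominal 5% there. No gene passed when either MMH-D3 array was left out; without MetE14/3 the counts were 52 and 154, and without WTE14/1 they were 9 and 18. At an unadjusted p under 0.05 there were 1558 genes. RLSC lay above both MMH-D3 arrays at 2623 genes and below both at 2690, together 42.2% of genes, against 33.3% by chance.

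The largest increases were in Cyba, a subunit of the NADPH oxidase, Fstl1, a secreted glycoprotein, and Myh10, a non-muscle myosin heavy chain. Cyba had a signal of 2583 ± 580 in RLSC against 1.96 ± 0.79 in MMH-D3, a difference of 8.74 (SE 0.47, limma adjusted p = 0.0137). Fstl1 was higher by 8.71 (SE 0.67) and Myh10 by 8.46 (SE 0.55). The MMH-D3 signals of Cyba, Fstl1 and Myh10 lay below the filter level of about 11.7, so the sizes and order of these differences depend on the pseudocount. Thbs1, encoding the matrix protein thrombospondin 1, differed by 7.01 (SE 0.74) and Cryab, a small heat shock protein, by 6.94 (SE 0.69). One of the 3 Cryab probe sets past the filter had the opposite sign.

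The largest decreases were in Crip1, Upk1b, Wfdc2, Gkn2, Bst1 and Gsta3. Crip1, a LIM domain protein, had a signal of 30.4 ± 29.1 in RLSC against 8550 ± 3038 in MMH-D3, a difference of -8.27 (SE 0.63, limma adjusted p = 0.0150). Upk1b, a uroplakin of urothelium and mesothelium, differed by -8.17 (SE 0.51), and Wfdc2, a secreted epithelial protein, by -7.66 (SE 0.55). Gkn2, a gastrokine of stomach epithelium, differed by -7.60 (SE 0.99) and its MMH-D3 arrays by 490 against 4206 in signal. The glutathione transferase Gsta3 differed by -7.44 (SE 0.92), with signals of 364 and 2628 on the MMH-D3 arrays. The RLSC signals of Gkn2, Bst1 and Gsta3 lay below the filter level of about 11.7, so the sizes and order of their differences depend on the pseudocount.

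**Figure D1:**
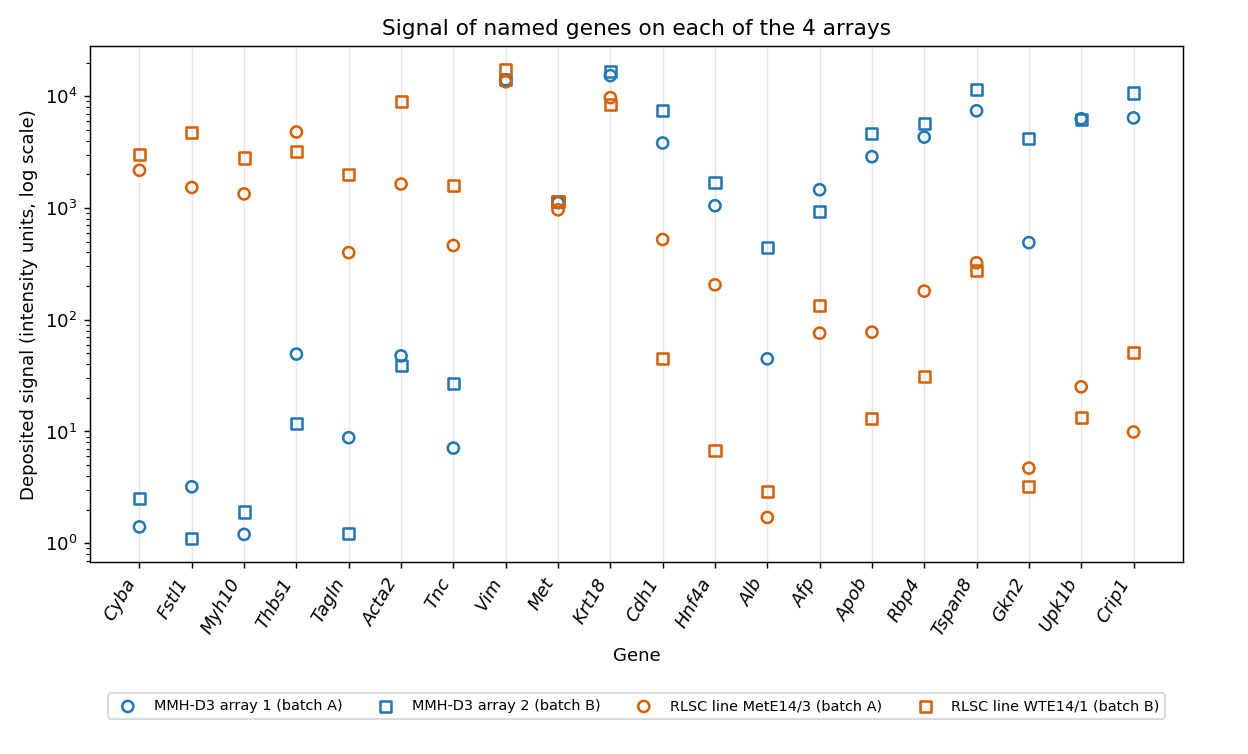
Deposited signal (intensity units, log axis) of 20 named genes on each array; each marker is 1 array, blue for MMH-D3 and orange for RLSC, circles for batch A and squares for batch B. Cyba lies at 2173 and 2993 in the RLSC lines and at 1.4 and 2.52 on the MMH-D3 arrays, while Vim and Met lie close together on all 4 arrays.

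The hepatocyte plasma protein list passed camera as lower in RLSC, but not with an estimated correlation or fry. Of 48 list genes with a probe set, 17 passed the filter and were tested; 4 were lower and none higher, and 12 were lower when adjusted over the list alone. The passing genes included Apob, the retinol carrier Rbp4 (-6.07, SE 0.86) and Ambp (-4.93, SE 0.73). Alpha-fetoprotein (Afp), a fetal liver product, differed by -3.50 (SE 0.47, limma adjusted p = 0.0392), with signals of 105 ± 41.5 in RLSC and 1190 ± 377 in MMH-D3; of its 4 probe sets past the filter, 3 had this sign. Albumin (Alb) was near the floor in RLSC (2.30 ± 0.85) and at 243 ± 280 in MMH-D3, where its arrays read 44.7 and 440; its difference of -4.75 (SE 0.96) did not pass (limma adjusted p = 0.102). Transthyretin (Ttr) did not pass either (-2.70, SE 0.83). The list median was -2.72 (camera adjusted p = 3.73e-11), and adjusted p = 0.347 with an estimated correlation. It was -2.85 within batch A and -2.97 within batch B, and the blocked median was -2.72 (camera adjusted p = 4.90e-12). The size depended on the choices: it was -0.71 without a filter (camera adjusted p = 4.01e-05) and -1.36 without MMH-D3 array 2.

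Liver-enriched transcription factors had a median of -1.63 over 20 tested genes (camera adjusted p = 0.000141; adjusted p = 0.347 with an estimated correlation). No single gene passed over all genes; adjusted over the list alone, 6 were lower and 1 higher. Hnf4a, a central regulator of hepatocyte genes, had signals of 205 in MetE14/3, 6.76 in WTE14/1, 1049 and 1687 on the MMH-D3 arrays (difference -4.90, SE 1.35, limma adjusted p = 0.202). Cebpa differed by -2.62 (SE 1.07), Cebpb by -1.92 (SE 0.53) and Xbp1 by -0.77 (SE 0.34), none passing. The list median was -0.94 within batch A and -1.82 within batch B, and -1.63 with the block (camera adjusted p = 5.41e-05), and -1.01 without MetE14/3.

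Epithelial junction and polarity genes had a median of -2.13 over 41 tested (camera adjusted p = 2.34e-13; adjusted p = 0.360 with an estimated correlation). The polarity gene Pard6b was lower (-3.09, SE 0.43) and no other member passed over all genes, while 22 were lower and 2 higher when adjusted over the list alone. E-cadherin (Cdh1) had signals of 522 in MetE14/3 and 45.2 in WTE14/1 against 3816 and 7390 in MMH-D3, a difference of -5.16 (SE 1.15) that did not pass. Epcam (-3.55, SE 0.88) and the keratins Krt18 (-0.77, SE 0.23) and Krt19 (-1.24, SE 0.44) did not pass; Krt18 signal was 9047 ± 947 in RLSC and 16010 ± 996 in MMH-D3. Its MMH-D3 signals are 100% and 99% of the array maxima, so Krt18 may be near saturation there and its difference poorly measured. Raw intensities were not examined. The median was -0.81 within batch A and -2.87 within batch B, and -2.13 with the block (camera adjusted p = 2.10e-13).

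The mesenchymal list passed camera as higher in RLSC, but not with an estimated correlation. Of 31 tested, 6 were higher, none lower and 25 did not pass, and 15 were higher when adjusted over the list alone. Smooth muscle actin (Acta2) differed by 6.20 (SE 0.80), with signals of 1638 and 8962 in the RLSC lines against 47.5 and 38.7 in MMH-D3, and tenascin C (Tnc) by 5.49 (SE 0.76). The list median was 1.66 (camera adjusted p = 3.10e-13; adjusted p = 0.268 with an estimated correlation; fry adjusted p = 0.0466). It was 1.77 within batch A and 1.72 within batch B, and 1.66 with the block (camera adjusted p = 2.10e-13). Vimentin (Vim), an intermediate filament of mesenchymal cells, was abundant in both groups, at 15360 ± 2674 in RLSC and 14060 ± 152 in MMH-D3 (difference 0.12, SE 0.18). These signals lie close to the array maxima of 15301 to 19155, so the measure may be near saturation and says little about a difference. The difference for the repressor Snai1 was 1.45 (SE 0.74), without passing.

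Matrix genes had a median of 1.35 over 35 tested (camera adjusted p = 4.99e-06; adjusted p = 0.347 with an estimated correlation), 0.45 within batch A and 1.64 within batch B; it was 0.84 without a filter and 0.42 without WTE14/1 (camera adjusted p = 0.0305). Thbs1 and the protease inhibitor Timp3 (6.57, SE 0.45) were higher and none lower; adjusted over the list alone, 9 were higher and 1 lower. Targets of TGF-beta and YAP had a median of 0.99 over 32 tested (camera adjusted p = 7.10e-08; adjusted p = 0.268 with an estimated correlation). Their medians were 0.76 and 1.13 within batches A and B, and Fstl1, Thbs1 and Tagln were higher. Adjusted over the list alone, 13 were higher and 1 lower. Wnt pathway genes had a median of 0.65 over 28 tested (camera adjusted p = 0.0114; adjusted p = 0.347 with an estimated correlation), 0.64 and 0.69 within batches A and B, and did not pass at the 60th percentile filter (0.18, camera adjusted p = 0.696). Without WTE14/1 the Wnt median was 0.295, and with the median of probe sets 0.31. The ligand Wnt5a was higher (4.87, SE 0.58) and the receptor Ror1 lower (-3.82, SE 0.57); adjusted over the list alone, 7 were higher and 2 lower.

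The cell cycle list passed camera, with a median unlike between the batches. It was 1.06 over 49 tested (camera adjusted p = 1.08e-08; adjusted p = 0.567 with an estimated correlation), but 0.02 within batch A and 2.18 within batch B, and the call was lost without MMH-D3 array 2 (camera adjusted p = 0.990). No member passed, over all genes or over the list alone. The ribonucleotide reductase subunit Rrm2 had signals of 7280 and 5302 in the RLSC lines, 7518 on MMH-D3 array 1 and 1469 on array 2. For Pcna, the replication clamp, the MMH-D3 arrays read 8136 and 2993 and the RLSC lines 7797 and 8102. Cholesterol biosynthesis genes had a median of -1.27 over 20 tested (camera adjusted p = 1.08e-08; adjusted p = 0.414 with an estimated correlation), -0.57 within batch A and -1.95 within batch B, and -0.78 without MMH-D3 array 2. None passed, although 17 lay below both MMH-D3 arrays; Hmgcs1 differed by -1.55 (SE 0.51) and Fdps by -1.32 (SE 0.47).

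Among other liver lists, glutathione and xenobiotic enzymes had a median of -0.90 over 29 tested (camera adjusted p = 0.000366; adjusted p = 0.414 with an estimated correlation), with Gsta3 lower and 5 lower over the list alone. Hepatocyte metabolism genes had a median of -0.30 over 20 tested (camera adjusted p = 0.0109; adjusted p = 0.347 with an estimated correlation); Aldh1a1 (-1.98, SE 0.58) and Glul (-1.45, SE 0.55) did not pass, and 1 gene was lower over the list alone. Cholangiocyte markers had a median of -0.58 over 18 tested (camera adjusted p = 0.0336; adjusted p = 0.542 with an estimated correlation), with the tetraspanin Tspan8 lower (-4.91, SE 0.36); adjusted over the list alone, 4 were lower and 3 higher. Stellate and mesothelial markers had a median of -0.83 over 17 tested (camera adjusted p = 0.0138; adjusted p = 0.347 with an estimated correlation). Upk1b, Bnc1 (-4.85, SE 0.65) and Wt1 (-4.30, SE 0.54) were lower. Members of both kinds went both ways without passing, such as the stellate markers Pdgfrb (4.70, SE 0.80) and Bambi (-0.86, SE 0.57) and the mesothelial Tbx18 (2.69, SE 0.55); adjusted over the list alone, 4 were lower and 2 higher. Within batches A and B the medians of these 4 lists were -0.43 and -1.21, -0.33 and -0.75, -0.20 and -1.76, and -0.68 and -0.88. Over all settings the medians ranged from -1.63 to -0.43 for glutathione, -1.98 to -0.19 for metabolism, -1.76 to -0.13 for cholangiocyte and -1.69 to -0.22 for stellate and mesothelial genes. Without MMH-D3 array 2 the glutathione list passed and the other 3 lists did not pass (adjusted p = 0.185, 0.214 and 0.214); without MMH-D3 array 1 the last 2 did not pass either (0.210 and 0.166). In all, 13 lists passed camera, the same 13 with batch as a block, and none with an estimated correlation. That variant recovered 0 of 20 simulated shifts of -1, so its lack of calls does not show that the lists were alike.

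The other 10 lists did not pass, although 4 of them did under at least 1 alternative. Adjusted over the list alone, at most 3 of their members were higher and 5 lower, both in the chemokine list. Hepatic progenitor markers had a median of -0.24, with Afp lower, and pluripotency markers -0.10; Klf4 differed by -3.71 (SE 0.59) without passing (limma adjusted p = 0.0553; 0.0267 with batch as a block, the only named gene whose call changed) and Klf5 by -0.96 (SE 0.57). Chemokine and cytokine genes had a median of -0.35, with Ccl9 higher (3.94, SE 0.54) and Il33 (-4.29, SE 0.62) and Fgf1 (-3.88, SE 0.53) lower. Neural and glial markers had a median of 0.21, with the intermediate filament Nes higher (5.31, SE 0.58). Interferon response genes had a median of -0.58 (Irgm1 1.14, SE 0.40; B2m 0.52, SE 0.32) and Hox genes -0.29 (Hoxa10 1.47, SE 0.52; Hoxb6 -0.35, SE 0.48).

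Imprinted growth genes had a median of 0.31 (Gnas 0.26, SE 0.23; Nap1l4 0.24, SE 0.40). Haematopoietic and macrophage markers had a median of -0.04 and a mean of 0.10, with camera's direction up (Cd14 -3.20, SE 0.53; Runx1 1.16, SE 0.54, with 4 of 6 probe sets of this sign). Endothelial markers had a median of 0.04 and a mean of -0.10, with camera's direction down (Flt1 -1.22, SE 0.53; Egfl7 -0.37, SE 0.53, with 3 of 4). Bone and cartilage markers had a median of 0.16 and a mean of 0.08, with camera's direction down (Bmp4 2.40, SE 0.87; Bmp2 -2.51, SE 0.81). Of the fixed genes, the receptor Met was similar in signal, 1055 ± 131 in RLSC and 1131 ± 20.8 in MMH-D3 (difference -0.06, SE 0.35), and its 2 probe sets had opposite signs. Cd34 differed by 2.99 (SE 0.57, limma adjusted p = 0.088). Col1a1, Ptprc, Kit and Pou5f1 lay below the filter.

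**Figure D2:**
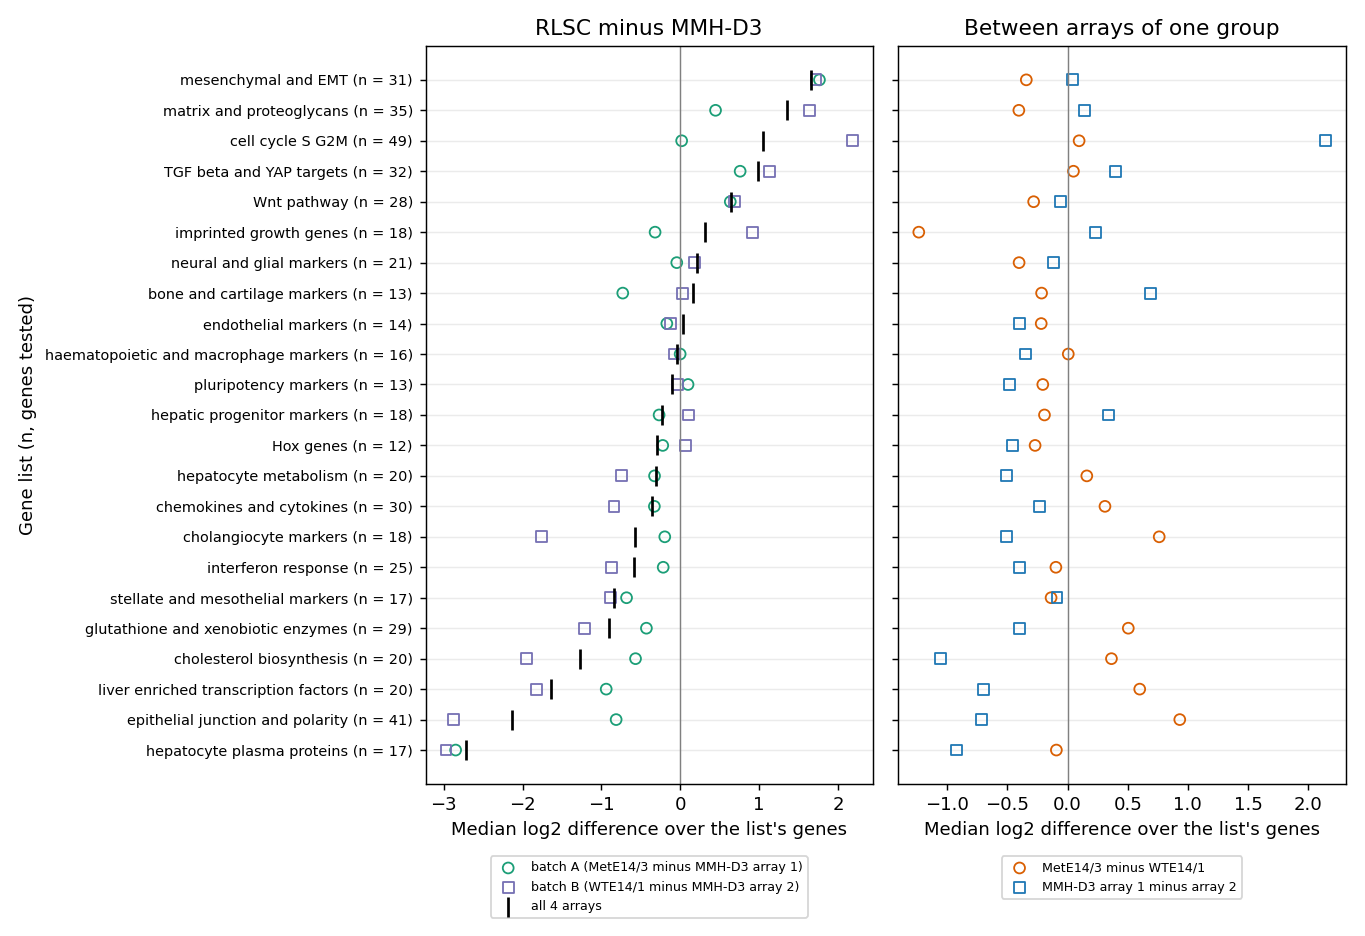
Median log2 difference over the tested genes of each of 23 lists; left, RLSC minus MMH-D3 within each batch and over all arrays, right, differences between the arrays of 1 group. The cell cycle list lies at 0.02 in batch A and 2.18 in batch B, and at 2.14 between the MMH-D3 arrays.

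The second comparison set the RLSC lines against each other, by a planned count of genes at least 4-fold apart, as each had 1 array. By list medians, epithelial genes leaned to MetE14/3 and imprinted and matrix genes to WTE14/1. At least 4-fold higher signals were found for 353 genes in MetE14/3 and for 293 in WTE14/1, a total of 646, while the MMH-D3 arrays differed as much at 751 genes. The count between the lines was no larger than that between arrays of 1 line. In a limma test added after the results had been seen, which took its spread from the MMH-D3 pair, no gene passed (smallest adjusted p = 0.0937), and 587 had an unadjusted p under 0.05. With 1 residual degree of freedom and MMH-D3 arrays from different batches, this does not show that the lines were alike. The values below are descriptions of 2 arrays.

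The tight junction gene Cldn2 had a signal of 3981 in MetE14/3 and 4.71 in WTE14/1, and 3039 and 2271 on the MMH-D3 arrays. The galectin Lgals4 had signals of 2481 and 17.2 in these lines. Ifi202b, Rgs20 and Nap1l2 differed by 6.89, 6.57 and 6.43 on the log2 scale, MetE14/3 minus WTE14/1. Pdxdc1 differed by 6.73, but its direction turned to -0.61 with the median of its 4 probe sets. Over the epithelial list, the lines differed by a median of 0.93 (percentile 100 of random lists), with 9 genes at least 4-fold higher in MetE14/3 and 1, Cldn6, in WTE14/1. The MMH-D3 arrays differed by -0.72 over this list (percentile 0). Cholangiocyte markers (median 0.76), including Anxa13 (5.65) and Pkhd1 (4.56), and glutathione and xenobiotic enzymes (median 0.51), including Gsta4 (4.05) and Aldh3a1 (3.55), were also at percentile 100, with the MMH-D3 arrays at 1.55 and 0.59. Liver-enriched transcription factors had a median of 0.60 (percentile 99.88, MMH-D3 arrays at percentile 0.25). Of these, 3 were at least 4-fold higher in MetE14/3, including Hnf4a at 4.48 and Onecut2 at 4.11. The 2 at least 4-fold higher in WTE14/1 were Cebpa (-3.22) and Creb3l3 (-2.225). Cdh1 differed by 3.74 and Epcam by 2.04.

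The chemokine Cxcl12 had a signal of 2417 in WTE14/1 and 1 in MetE14/3, and 5.3 and 6.64 on the MMH-D3 arrays. Hmgn3, Peg3, Ctsz, Sox11 and Cldn6 had differences of -8.00, -7.87, -7.46, -7.29 and -7.23. Over imprinted growth genes the median was -1.24 (percentile 0; MMH-D3 arrays 87.25), and 8 of 18 were at least 4-fold higher in WTE14/1 and none in MetE14/3. These included Peg3, with signals of 2265 in WTE14/1 and 5.9 in MetE14/3, and Sgce, with 712 and 0.9. Matrix genes had a median of -0.41 (percentile 0.19; MMH-D3 arrays 80.29), with Col11a1 at -5.65 and Vcan at -4.92. Mesenchymal genes had a median of -0.34 (percentile 1.32; MMH-D3 arrays 65.61), with Lox at -4.77 and Loxl1 at -3.16. Hepatocyte plasma protein genes had a median of -0.09 (percentile 42.66; MMH-D3 arrays 0.2), with Rbp4 at 2.71 and Itih2 at -4.76. Cell cycle genes had a median of 0.10 (percentile 79.18; MMH-D3 arrays 100). The MMH-D3 arrays, of 1 line, were thus as extreme on several lists as the RLSC lines. Each RLSC line lay in its own batch. After the difference between the MMH-D3 arrays of the same batches was subtracted, 1451 genes differed at least 4-fold. The subtraction also adds the spread of the MMH-D3 pair. The SD of log2 differences was 1.01 between the lines, 1.009 between the MMH-D3 arrays and 1.377 after subtraction. The larger count therefore does not show more differences between the lines.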

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

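All tests of explanations in this part were chosen after the results had been seen. The lines of 1 group moved in opposite directions from MMH-D3 at 20 of 102 named genes, with both MMH-D3 arrays between them. The difference was not tested when these were picked out. The limma test between the lines added later cannot decide. It had 1 array per line and took its spread from MMH-D3 arrays of different batches. With all orders of the 4 arrays equally likely, 16.7% of genes would lie so, a rough yardstick since the batches pair the arrays. The share was 19.6% of the named and 11.4% of all tested genes, and 19 of the 20 had been named because the lines differed. MetE14/3 was above and WTE14/1 below for Cldn2 (MetE14/3 minus WTE14/1, 9.06 on the log2 scale), Nap1l2 (6.43), Ccl2 (5.63), Pkhd1 (4.56) and Prom1 (4.32). The opposite held for Cxcl12 (-8.96), Hmgn3 (-8.00), Peg3 (-7.87), Sox11 (-7.29), Cldn6 (-7.23), Sgce (-7.19), Bex1 (-7.03), Col11a1 (-5.65), Crmp1 (-5.41), Vcan (-4.92), Ror2 (-4.50), Msx2 (-3.61), Gpr182 (-2.34), Hoxa5 (-2.17) and Met (-0.31). List medians did so for imprinted growth genes (-1.24), neural and glial markers (-0.40) and Hox genes (-0.27).

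Control probe sets, used only to define the batches, and probe sets without a single symbol, tested only at probe set level, also held signals. The poly-A controls were 10.59-fold higher in batch A, and the 5' control for 18S ribosomal RNA read 1632 in MetE14/3 against 243 to 268 on the other arrays. At probe set level, 22 probe sets without a single gene symbol passed the threshold, of 198 passing in all.

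Cell cycle genes were lower on MMH-D3 array 2 than on array 1, with a median difference of 2.14 for array 1 minus array 2. A batch difference would shift the RLSC lines of the same batches alike, but their median difference was 0.096. A single scaling factor would move all lists alike. In the values as deposited, before quantile normalization removed such a factor, cell cycle genes differed by 2.222 and cholesterol biosynthesis genes by -1.038, a gap of 3.26 that no factor changes. The gap argues against a single scaling factor. The value of 0.096 argues against a batch difference only if no difference between the 2 RLSC lines offset it, which 1 array per line cannot show. A difference in growth state between the MMH-D3 samples remains open and untested, since the labels give no growth state and do not say whether the samples came from separate cultures.

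Epithelial list genes had larger signals in MetE14/3 than in WTE14/1 by median (0.93), a value without a test. Not all genes of MMH-D3 went this way, as Ctsz, at 3191 and 2798 on the MMH-D3 arrays, read 0.6 in MetE14/3 and 796 in WTE14/1. If MMH-D3 RNA had been mixed into the MetE14/3 sample, genes abundant in MMH-D3 would appear there at about 1 share of their MMH-D3 level. Over 26 genes with signals of at least 1000 on both MMH-D3 arrays and under 50 in WTE14/1, the 90th percentile of that share was 17.8 times the 10th, from 0.401% for Upk1b to 150% for Cldn2. Whatever their WTE14/1 signal, 4 of 1577 genes abundant on both MMH-D3 arrays stood below 1% of their MMH-D3 level in MetE14/3 and 14 below 5%, against 22 and 42 in WTE14/1. The smaller counts in MetE14/3 go with a mixture, but the spread of shares argues against 1 share of MMH-D3 RNA as the whole cause. A batch difference would raise the epithelial genes on MMH-D3 array 1 as well, but their median difference between the MMH-D3 arrays was -0.719. This counts against a batch difference only if the MMH-D3 samples did not otherwise differ, which was not tested. Whether the cyto-Met transgene plays a part cannot be told apart from other differences between the lines, since there was 1 line per genotype, and so the transgene may or may not contribute. Met read 963 in MetE14/3 and 1148 in WTE14/1, so the arrays do not show the transgene, and whether the Met probe sets detect it was not tested.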

How the results depend on the processing

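The batch settings and the test between the RLSC lines were added after seeing the data; all others were planned. The counts of 50 higher and 65 lower genes became 4 and 5 without a filter, 0 and 0 at an adjusted p under 0.01, and 92 and 106 over all probe sets. The first has more genes tested; all 9 of its calls were shared. Leaving out 1 array gave 0 to 52 higher and 0 to 154 lower genes: none without MMH-D3 array 1 or array 2 (2197 and 1000 genes at an unadjusted p under 0.05 in limma), 52 and 154 without MetE14/3, and 9 and 18 without WTE14/1; the lone array was assumed to vary like the other group. Within batch A, 386 genes were at least 4-fold higher and 443 lower, and within batch B 728 and 941. No pairing by replicate number was possible because the RLSC lines carry none in the labels; batch served as the block.

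All 4 main lists lost their call with an estimated correlation, with unchanged medians: hepatocyte plasma proteins -2.72 (adjusted p = 0.347), transcription factors -1.63 (0.347), epithelial genes -2.13 (0.360) and mesenchymal genes 1.66 (0.268). With fry the first 3 did too (0.111, 0.245 and 0.216). In simulations, with genes varying independently, the estimated correlation recovered 0 of 20 shifts. This does not show that the calls at the preset correlation hold. The 646 genes between the RLSC lines became 400 with a pseudocount of 16, 386 with a 60th percentile filter and 2468 at 2-fold. Subtracting the MMH-D3 arrays, which adds their spread, gave 1451, and the added limma test passed 0.

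Over all settings the medians of the 13 lists with a call ranged as follows: plasma proteins -4.363 to -0.712, transcription factors -2.031 to -0.939, epithelial -2.873 to -0.813, mesenchymal 1.319 to 2.07, matrix 0.421 to 1.638, TGF-beta and YAP 0.76 to 1.129, Wnt 0.179 to 0.868, cell cycle 0.017 to 2.183, cholesterol -1.949 to -0.567, glutathione -1.634 to -0.429, hepatocyte metabolism -1.977 to -0.192, cholangiocyte -1.763 to -0.131, stellate and mesothelial -1.685 to -0.224. Calls were also lost in other lists. Cholangiocyte markers lost theirs with 75th percentile scaling, a pseudocount of 1, the median of probe sets, and without MMH-D3 array 1, MMH-D3 array 2 or WTE14/1 (medians -0.131 to -0.491). Stellate and mesothelial markers lost theirs without a filter (-0.224) and without MMH-D3 array 1 (-0.363) or 2 (-0.278). Wnt genes lost theirs at the 60th percentile (0.179), with medians of 0.295 without WTE14/1 and 0.31 with the median of probe sets. Without MMH-D3 array 2, cell cycle (0.017, adjusted p = 0.990) and hepatocyte metabolism (-0.232, 0.185) did. Calls were gained by chemokines with the median of probe sets (-0.453, adjusted p = 0.0386) and without MetE14/3 (-0.623, 0.0201), by neural and glial markers in the same settings (1.492, 0.0202; 0.398, 0.0201) and by pluripotency markers at the 60th percentile (-0.962, 0.0479).

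Directions turned in the following cases, and the cause was not tested. As deposited: haematopoietic 0.203, pluripotency 0.083. With 75th percentile scaling: haematopoietic 0.084, Vim -0.003. With a pseudocount of 1: haematopoietic 0.082. With one of 16: endothelial -0.038. Without a filter: bone -0.312, endothelial -0.094, haematopoietic 0.011, pluripotency 0.072. At the 60th percentile: endothelial -0.796, haematopoietic 0.268, Hox 1.296. With the median of probe sets: endothelial -0.434, pluripotency 0.2, Gnas -0.138, Met 0.107, Pdxdc1 -0.611. Within batch A: bone -0.729, endothelial -0.17, imprinted -0.319, neural -0.044, pluripotency 0.099, Klf5 0.099, Nap1l4 -0.283, Cxcl12 -1.083. Within batch B: endothelial -0.12, progenitor 0.107, Hox 0.07, Met 0.044. With each array left out, ranges that crossed 0 were: bone -0.157 to 0.685, endothelial -0.128 to 0.208, haematopoietic -0.111 to 0.064, progenitor -0.377 to 0.031, Hox -0.343 to 0.082, imprinted -0.118 (adjusted p = 0.0242, without WTE14/1) to 0.763 (adjusted p = 0.000705, without MetE14/3), interferon -0.717 to 0.027, pluripotency -0.381 to 0.152. For genes they were Egfl7 -0.79 to 0.049, Met -0.22 to 0.096, Nap1l4 -0.143 to 0.602 and Rrm2 -0.15 to 2.129. Low signals limit the precision, since folds near the floor depend on the pseudocount.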

Other observations

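The list of stomach and intestine genes used here was drawn, after the results had been seen, from a wider set of genes whose values had been looked at, and all tests on it were chosen after that. Of its 30 genes, 23 were tested, 4 were lower in RLSC (Gkn2, Anxa10, Gata5 and Tspan8) and the others did not pass. The median difference was -3.74 (-1.76 within batch A and -5.41 within batch B), given as a description since the list was picked from these data, and 3 of the genes also belong to other lists. Lgals4 had signals of 8578 and 13971 on the MMH-D3 arrays, the brush border annexin Anxa13 7718 and 11737, and the intestinal cadherin Cdh17 5654 and 6823. MetE14/3 also held some of them, with signals of 2481 for Lgals4, 2293 for Lgals2, 1515 for Cdh17, 991 for Krt20 and 907 for Anxa13. Ctse differed by 0.08 between the groups, and Cldn18 read 32.4 and 24.1 on the MMH-D3 arrays. Several read far higher on array 2 than on array 1: Dmbt1 6087 against 674, Sult1c2 2886 against 282, and Fabp2, the intestinal fatty acid binding protein, 827 against 62.6. Gkn1 reached 11.3 and 85.1, and Cdx2 was 510 and 433 in MMH-D3 against 370 and 245 in the RLSC lines.

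Each batch held 1 array of each group, so an offset shared by the arrays of a batch cancels in the difference between the groups. Such an offset cannot produce the difference, whichever genes are taken. The weaker of the within-batch medians was -1.763, but the genes were picked from these same arrays, so it is no further test. A batch difference that acts unlike on the groups was not tested. The genes had been picked from values of 1 probe set each. For the 8 with further probe sets past the filter, 100% of 11 such sets had smaller values in RLSC. Sets low on all arrays had been removed by the filter before this count. The share therefore cannot decide whether single unspecific probe sets play a part. The other 15 genes had no further probe set past the filter, so this stays open for all of them. Differences between the MMH-D3 arrays ran from -3.35 to 0.79, with an SD at percentile 97.97 of random gene sets of the same level. Reading this against cells of another type would need their profile, which was not measured. Such cells among MMH-D3, and a digestive tract program in MMH-D3 shared in part by MetE14/3, both remain open.

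Xist, Uty and Kdm5d were looked at after the results had been seen. Xist, the RNA of the inactive X chromosome, had a signal of 1361 in MetE14/3, 17.4 in WTE14/1, and 3.9 and 25.5 on the MMH-D3 arrays. The Y-linked genes Uty and Kdm5d had signals of 304 and 193 in WTE14/1 and of 3.4 and 2 in MetE14/3, and of 15.1 and 14.4 or less in MMH-D3. These values involve no test.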
